A study of Mus musculus with 8 samples.

How the data were processed

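Hippocampal RNA-seq libraries of C57BL/6 mice were analysed from gene-level tables, 1 per library, for 8 libraries taken before fear conditioning. Groups and animal numbers were read from the sample titles: 2 WT and 2 KO numbers with 2 technical replicates each. The KO label refers to Pyk2, the product of Ptk2b.

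The authors deposited FPKM values with lower and upper confidence limits and a status for each gene, per the file headers. The submitters' processing notes name the mm10 genome, Bowtie (version 1) and HISAT, with no role given. The column layout is that of a Cufflinks gene table, but the program that computed the FPKM, its version and any scaling between libraries are not given in the sources used here. RNA was extracted with Trizol and libraries came from total RNA, per the labels' protocols, and no strand setting is given there, so overlapping genes cannot be separated. FPKM divide by length and library total, so very short genes reach high values from few fragments, and a change in a few abundant genes shifts all others.

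No counts were among the values used here, and fragment numbers were not recovered. The number that each confidence interval implies came out whole, within 0.05, for 22.9% to 24.6% of the low genes in each library. Summed over genes these implied numbers were 11.3 M to 14.1 M per library, and the relative depth from steps of low genes was 0.797 to 1.07 times that of the first library of WT1. These depths cover counting error only. The planned test on counts was therefore replaced by the planned fallback for FPKM, limma with a trended variance. The planned comparison of technical replicates by counts was replaced by the difference of each gene against the 95% range from the deposited intervals (an interval of 2 SD on each side, genes with at least 10 implied fragments).

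Each table held 55241 rows for 55188 genes; the 53 extra rows repeat a gene identifier and were summed. In all, 12 values with a status other than OK were treated as missing. They include mt-Co1 and mt-Ts1, listed at 0 in the first library of KO1. Of the genes, 54928 were found in GENCODE M21, 99.4% of these with the same coordinates after counting starts from 1. Coordinates are those of the deposited tables, and gene types come from GENCODE M21. A set of ubiquitous genes such as Actb and Gapdh was above 0 in every library.

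Technical replicates were averaged per animal, and genes with at least 0.5 FPKM in 2 animals were kept (16667 genes). This minimum was chosen after the values were seen. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, KO minus WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount understates fold changes of low genes. Gene lists (38) were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and the rotation test fry as alternatives. The result of 1 of these lists is not reported here; it stays in the totals of lists tested and called. Adjusted p-values in the text come from limma unless an exact test is named. Figures were drawn with matplotlib 3.10.9.

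Genes were named by a rule fixed before the data were examined. It takes Ptk2b, then among genes past the threshold with a mean of at least 1 and the same direction in all 4 pairs of a KO and a WT animal, the 12 largest rises and 12 largest falls. The planned mean in log2 CPM was read as a mean of log2(FPKM + 1) of at least 1, a reading made after the values were seen. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as not passing, and of each list up to 4 members with the smallest p. Not all of the latter are printed. Genes named in the text beyond these, Ttr, Enpp2, Folr1, Rarres2, Foxj1, Tmem212, Ccdc153, Alas2, Col1a1, Col1a2, Col3a1, Scara5, Nefm and Ptk2, and the Y-linked genes, were chosen after their values were seen.

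The procedure was tested on simulated data of 2 against 2 animals with the means of the 16667 genes. Noise was independent between genes, with a variance drawn at random for each gene around the fitted trend. In each of 5 runs 100 genes were changed by 1 and 100 by 2 on the log2 scale, all of a log2 mean of at least 3. The procedure recovered 95.4% and 99.2% of these, with 6.03% false calls on average, and made 0.2 calls on average where no gene was changed. In the real data choroid plexus markers had an estimated inter-gene correlation of 0.864, and 0 passed over all genes. Such genes can also vary widely between animals of 1 group, as Ttr did at 180 and 934 FPKM in the animals labelled KO. Noise drawn around the fitted trend need not reach that spread. The simulated shares therefore do not give the power for genes that vary together or vary that widely.

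Alternatives were another scaling, other minimums and pseudocount, single technical replicates, all libraries as units, the animal number as a block, each animal left out and other thresholds, and further ones were chosen after seeing the data. Tests that need counts were not run.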

Results

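RNA from mouse hippocampus, the brain region needed for contextual fear memory, was sequenced before fear conditioning in C57BL/6 wild-type (WT) mice and in mice labelled as knockouts (KO) of Pyk2, a calcium-sensitive tyrosine kinase encoded by Ptk2b. The 8 libraries were 2 numbered WT units and 2 numbered KO units with 2 technical replicates each, and each unit was treated as 1 animal (n = 2 per group). The labels do not state that each number is a separate mouse, so the p-values measure the spread between these units. Each library listed FPKM, fragments scaled by transcript length and library total, for 55188 genes, of which 26482 to 27871 were above 0. Total read numbers were not among the values used here. Taken as counting error alone, the width of the deposited confidence intervals would imply 11.3 M to 14.1 M fragments per library, with overlapping ranges in both groups. Fragment numbers were not recovered, so these figures are rough. The sums of FPKM were 489153 to 506251. The design asks which hippocampal transcripts differ between WT and Pyk2-deficient mice at baseline.

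The targeted gene was examined first. Ptk2b (ENSMUSG00000059456, chromosome 14, 66153257 to 66281052 in mm10, protein-coding) was not lower in the libraries labelled KO. It stood at 217 ± 21 FPKM in WT and 273 ± 6.33 FPKM in the animals labelled KO (SD, n = 2 each), 26.0% higher. The 4 libraries labelled KO gave 277, 279, 264 and 274 FPKM, above all 4 WT libraries at 232, 232, 203 and 202 FPKM. On the log2(FPKM + 1) scale the difference was 0.34 with a standard error (SE) of 0.07 and a 95% interval of 0.15 to 0.52, and it did not pass the threshold in limma (adjusted p = 0.158). An exact two-sided permutation test of the 4 animals gave p = 0.333, the smallest value that 2 against 2 animals allow. The level of Ptk2b therefore does not bear out the KO label, and it cannot refute it. A value summed over the whole gene shows neither the loss of an exon nor the loss of the protein, so every direction below is given for the libraries labelled KO, as labelled.

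**Figure D1:**
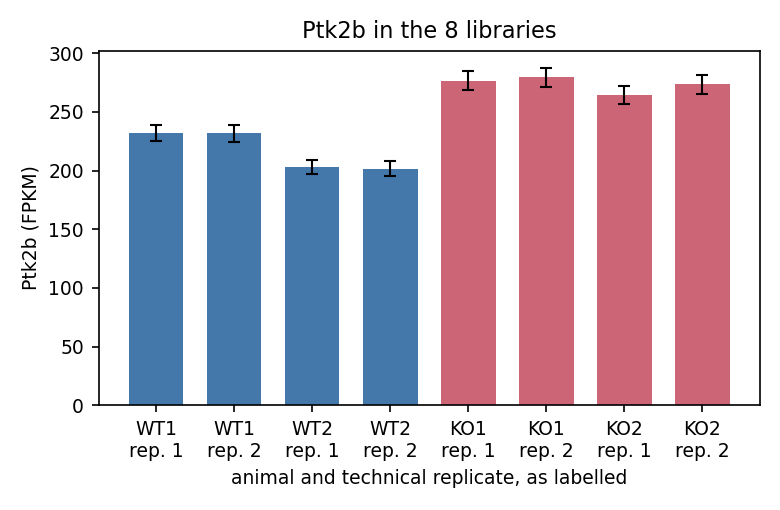
Ptk2b in FPKM (vertical axis, from 0) in each of the 8 libraries (horizontal axis), blue for WT and red for the libraries labelled KO; error bars are the confidence limits deposited with each value. The WT libraries lie between 202 and 232 FPKM and those labelled KO between 264 and 279 FPKM.

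Protein-coding genes past the threshold fell in the animals labelled KO, a direction that rests on labels the Ptk2b level did not bear out. Cox8b, an isoform of a cytochrome c oxidase subunit (ENSMUSG00000025488, chromosome 7, 140898945 to 140900446), fell from 16.0 ± 2.14 FPKM in WT to 1.69 ± 0.433 FPKM (SD, n = 2 each), a log2 fold change of -2.66 (SE 0.14, adjusted p = 0.0372). Ucp2, a mitochondrial carrier protein (ENSMUSG00000033685, chromosome 7, 100493337 to 100502020), fell from 33.1 ± 1.19 to 13.4 ± 1.29 FPKM, a log2 fold change of -1.25 (SE 0.07, adjusted p = 0.0373). The adult alpha-globin genes Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) and Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298) fell by 1.00 and 0.95 on the log2 scale, from 77.2 ± 4.99 to 38 ± 1.1 FPKM and from 93.2 ± 6.87 to 47.7 ± 0.899 FPKM. These globins are near-identical copies, so the division of reads between them is uncertain. Ppp1r1b, a phosphatase inhibitor regulated by dopamine and cAMP (ENSMUSG00000061718, chromosome 11, 98348404 to 98357796), fell from 50.9 ± 1.98 to 28.2 ± 0.220 FPKM, a log2 fold change of -0.83 (SE 0.04, adjusted p = 0.0372). Pcp4l1, a relative of the calmodulin-binding protein Pcp4 (ENSMUSG00000038370, chromosome 1, 171173262 to 171196268), fell from 52.6 ± 2.32 to 31.0 ± 0.201 FPKM, a log2 fold change of -0.74 (SE 0.05, adjusted p = 0.0373). The annotated spans of Ucp2 and Ppp1r1b each overlap another gene, so their reads cannot be fully separated from it. In these 6 genes both animals labelled KO lay below both WT animals. Markers of choroid plexus and blood were lower in the same animals, as given with the gene lists.

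The remaining calls were short noncoding RNAs whose values rest on single libraries. Scarna17, a small Cajal body RNA (ENSMUSG00000088689, chromosome 18, 74778391 to 74778469), was listed at 16.8 and 0 FPKM in the technical replicates of WT1, at 23.8 and 0 FPKM in those of WT2, and at 0 in all 4 libraries labelled KO (adjusted p = 0.0372). Gm47296, annotated as a miRNA gene (ENSMUSG00000104880, chromosome 11, 5038204 to 5038307), and Gm22208, annotated as an snRNA gene (ENSMUSG00000084607, chromosome 15, 34531714 to 34531823), were below the level set for naming and were named after their values were seen. Gm47296 was at 3.61 and 0 FPKM in WT1, 3.54 and 0 FPKM in WT2, and at or below 0.000515 FPKM in the libraries labelled KO. Gm22208 was at 2.76 and 0 FPKM in WT1, 0 and 2.98 FPKM in WT2, and at 0 in the libraries labelled KO. No gene higher in the animals labelled KO passed the threshold. The 5 with the smallest p were Gm26427, an snRNA gene at 2.18 ± 0.555 FPKM and listed at 0 in every WT library, Gm24260, an snRNA gene at 2.30 ± 0.247 and 5.85 ± 0.928 FPKM, Gm26602 at 42.9 ± 0.470 and 52.9 ± 0.404 FPKM, Lingo1, and the pseudogene Gm37545 at 0.0226 ± 0.0320 and 0.618 ± 0.0290 FPKM (WT first). Lingo1, a receptor component that restrains myelination, stood at 91.4 ± 1.66 FPKM in WT and 111 ± 0.652 FPKM in the animals labelled KO, a log2 fold change of 0.28 (SE 0.04, adjusted p = 0.0981), so it did not pass. Gm47296, Gm26427, Gm24260, Gm26602 and Gm37545 overlap other annotated genes, so their reads cannot be fully separated from those.

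In all, limma called 9 of 16667 tested genes at a Benjamini-Hochberg adjusted p under 0.05, with 0 higher and 9 lower in the animals labelled KO. At an unadjusted p under 0.05 there were 2591 genes, 685 higher and 1906 lower, against 833 if no gene differed. The share lower depended on the scaling: 73.6% here, 63.0% of 2657 genes after median-of-ratios scaling and 53.3% of 2487 after quantile normalization. Both animals of a group lay beyond both of the other group for 49.1% of genes, where chance gives 33.3%. The count of limma calls was 0 without WT1, 0 without WT2 (1631 and 1327 unadjusted), 1 without KO1 (higher, and none of the 9) and 128 without KO2 (14 higher, 114 lower), where the lone animal of a group is assumed to vary like the other group, and it was 20 without the first library of KO1. With no filter on low values 0 of 34097 genes passed (3741 unadjusted), and the minimum of 0.5 FPKM in 2 animals was chosen after the values were seen.

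**Figure D2:**
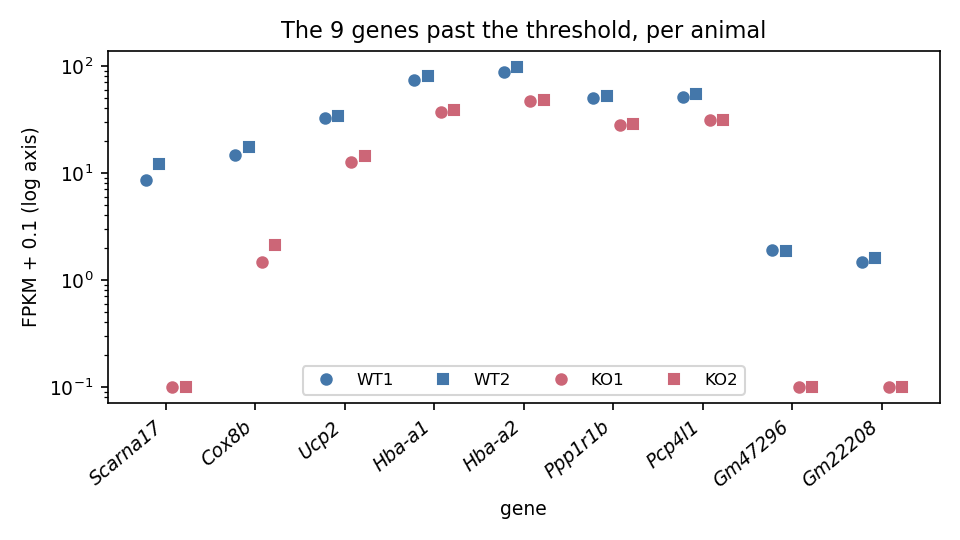
FPKM + 0.1 on a log axis (vertical) for the 9 genes past the threshold (horizontal), 1 point per animal, circles for number 1 and squares for number 2 of each group, blue for WT and red for the animals labelled KO. All 9 genes are lower in both animals labelled KO, and Scarna17 and Gm22208 are listed at 0 there.

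Among 38 gene lists fixed before the data were examined, choroid plexus and ependyma markers stood furthest apart. The median log2 fold change of the 22 measured members was -2.17, and the list fell as a set (camera with a preset correlation, adjusted p = 2.37e-15; adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 19 members fell, 0 rose and 3 did not pass, while 0 passed when adjusted over all genes. The members with the smallest p were Calml4, a calmodulin-like gene at 19.2 ± 2.14 FPKM in WT and 3.01 ± 1.48 FPKM in the animals labelled KO (log2 fold change -2.38, SE 0.26), the growth factor binding protein gene Igfbp2 (-2.08, SE 0.25), the metalloreductase family gene Steap1 (-2.17, SE 0.28) and the membrane protein gene Tmem72 (-1.69, SE 0.25). Other members were picked after their values were seen: Ttr, the transthyretin gene that choroid plexus expresses at very high level, was at 3366 and 6325 FPKM in the WT animals and at 180.0 and 934 FPKM in the animals labelled KO (log2 fold change -3.49, SE 0.80). Enpp2, which encodes autotaxin, was at 805 ± 169 and 171 ± 111 FPKM, and Folr1, a folate receptor, at 49.8 ± 8.70 and 7.02 ± 6.57 FPKM. Rarres2 and the ependymal genes Tmem212 and Ccdc153 were the members that did not pass, with log2 fold changes of -0.51, -0.52 and -0.57. All 22 members had a lower mean in the animals labelled KO, and the median was -2.16 after median-of-ratios scaling.

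Blood and meningeal markers were lower in the same animals. All 5 measured blood markers of the 14 listed fell when adjusted over the list alone, and 2 of them, Hba-a1 and Hba-a2, also when adjusted over all genes (camera adjusted p = 5.15e-08; adjusted p = 0.536 with an estimated correlation). The beta-globin genes Hbb-bs and Hbb-bt, near-identical copies as well, were at 93.2 ± 6.74 and 37.4 ± 2.46 FPKM in WT and at 47.0 ± 3.51 and 20.1 ± 1.02 FPKM in the animals labelled KO. Of the 17 measured meningeal fibroblast markers, 4 fell adjusted over the list alone, 13 did not pass, and 0 passed over all genes (camera adjusted p = 4.54e-06; adjusted p = 0.610 with an estimated correlation). The members that fell were the growth factor genes Bmp6 (log2 fold change -1.22, SE 0.09) and Igf2 (-2.04, SE 0.33) and the transporter genes Slc13a4 (-1.68, SE 0.21) and Slc6a20a (-0.83, SE 0.10), and Igf2 is also on the choroid plexus list. The fibroblast collagen genes Col1a1 and Col1a2 did not pass, with log2 fold changes of -0.17 (SE 0.09) and -0.42 (SE 0.13).

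**Figure D3:**
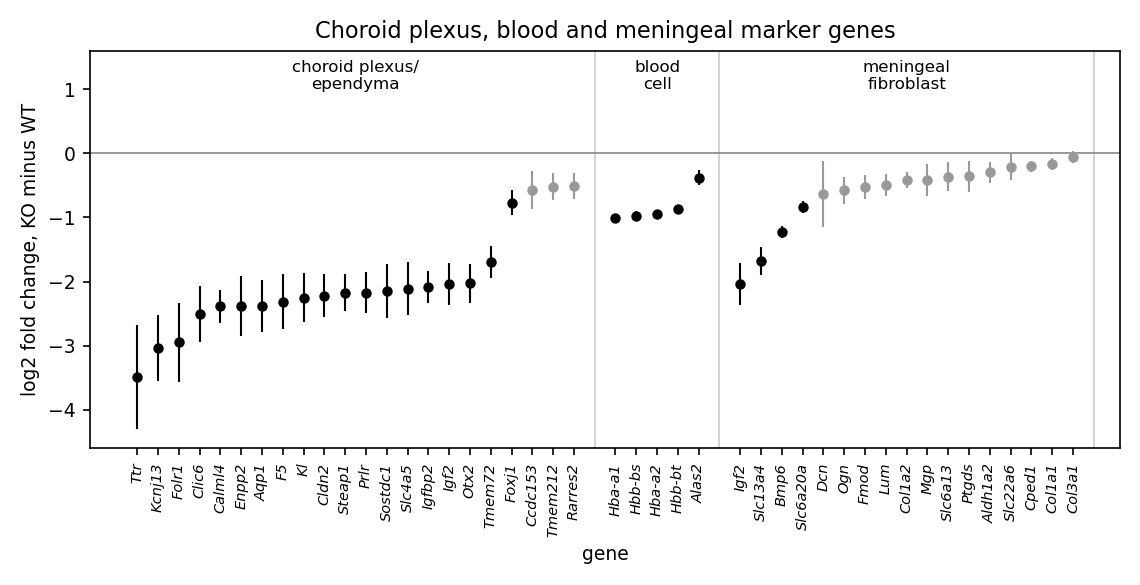
Log2 fold change of log2(FPKM + 1), animals labelled KO minus WT (vertical), for each measured gene (horizontal) of the choroid plexus and ependyma, blood and meningeal lists; bars are 1 SE, black marks an adjusted p under 0.05 over the list alone and grey the others. Points reach from -3.49 for Ttr to -0.06 for Col3a1.

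Vessel and interferon lists were lower by less. Of 20 endothelial and pericyte markers, 1 fell adjusted over the list alone and 0 over all genes (median log2 fold change -0.12, camera adjusted p = 0.0174; adjusted p = 0.619 with an estimated correlation). That member was Pltp, a phospholipid transfer protein, at 47.8 ± 2.06 FPKM in WT and 26.6 ± 4.29 FPKM in the animals labelled KO. The set call of this list ended without WT2 (adjusted p = 0.204) and after quantile normalization (adjusted p = 0.0679). Of 26 interferon response and antigen presentation genes, 4 fell adjusted over the list alone and 0 over all genes (median log2 fold change -0.13, camera adjusted p = 0.0443; adjusted p = 0.774 with an estimated correlation). These were the antiviral membrane protein gene Bst2 (log2 fold change -0.82, SE 0.17), the restriction factor gene Ifitm3 (-0.41, SE 0.08), the peptide transporter gene Tap2 (-0.38, SE 0.08) and the class I gene H2-K1 (-0.39, SE 0.09), whose reads are hard to divide among similar class I genes. The interferon set call ended without WT1, after quantile normalization (adjusted p = 0.0868) and without the first library of KO1 (adjusted p = 0.0606). Without KO2 the direction of the camera test, which sets a list against all other genes, turned. The list median itself stayed negative with any 1 animal left out (-0.29 to -0.032). Choroid plexus and blood markers were lower in the same animals.

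Synaptic gene lists were higher as sets in the animals labelled KO, by small amounts and with no single member passing. Genes of synaptic vesicle release had a median log2 fold change of 0.10, with 27 of 31 members higher (camera adjusted p = 1.03e-08; adjusted p = 0.536 with an estimated correlation). Examples are Rims1, an active zone organiser, at 46.3 ± 0.890 FPKM in WT and 54.2 ± 2.23 FPKM in the animals labelled KO, and the SNARE gene Snap25 at 828 ± 13.6 and 950.0 ± 38 FPKM. Slc32a1, the vesicular GABA transporter, went the other way at 37.9 ± 3.19 and 31.5 ± 1.38 FPKM. Memory kinases and phosphatases had a median of 0.13, with 27 of 31 higher (adjusted p = 1.64e-08; adjusted p = 0.536 with an estimated correlation), among them Camk4 at 13 ± 0.199 and 16.9 ± 1.38 FPKM. Postsynaptic density scaffolds had a median of 0.10, with 26 of 28 higher (adjusted p = 3.53e-08; adjusted p = 0.536 with an estimated correlation), among them Shank1 at 59.4 ± 0.278 and 67.2 ± 1.07 FPKM. Adjusted over each list alone, as over all genes, 0 members of these lists passed. The choroid plexus and blood markers moved the opposite way in the same animals.

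Receptor and channel lists were also higher as sets, with 0 members past the threshold either over all genes or adjusted over the list alone. Potassium channels had a median log2 fold change of 0.10, with 28 of 34 higher (camera adjusted p = 4.54e-06; adjusted p = 0.536 with an estimated correlation). GABA and glycine receptors had a median of 0.11, with 15 of 19 higher (adjusted p = 0.00304; adjusted p = 0.536 with an estimated correlation), including Gabra5 at 71.3 ± 4.23 FPKM in WT and 83.3 ± 3.51 FPKM in the animals labelled KO. Glutamate receptors had a median of 0.05, with 17 of 24 higher (adjusted p = 0.00529; adjusted p = 0.536 with an estimated correlation), including Grm2 at 14.6 ± 0.974 and 18.6 ± 1.92 FPKM. Voltage-gated calcium channels had a median of 0.08, with 12 of 16 higher (adjusted p = 0.0174; adjusted p = 0.536 with an estimated correlation). The calcium channel call ended without WT2 (adjusted p = 0.09), without KO2 (adjusted p = 0.0528) and after quantile normalization (adjusted p = 0.120). With 1 animal left out, the medians were 0.05 to 0.15 for potassium channels, 0.05 to 0.09 for GABA and glycine receptors and 0.03 to 0.06 for glutamate receptors, with the set calls kept, and 0.02 to 0.06 for calcium channels. Choroid plexus and blood markers, with medians of -2.17 and -0.95, moved the opposite way in the same animals.

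Immediate early genes, which neuronal activity induces, had a median log2 fold change of 0.14 with 25 of 33 members higher (camera adjusted p = 5.08e-05; adjusted p = 0.612 with an estimated correlation). Adjusted over the list alone 1 member rose, the antiproliferative gene Btg2, from 7.37 ± 0.398 FPKM in WT to 10.4 ± 0.497 FPKM in the animals labelled KO, and 0 passed over all genes. Fos stood at 16.7 ± 0.360 and 23.8 ± 4.35 FPKM and did not pass. Microglia markers had a median of 0.09 with 16 of 20 higher (adjusted p = 0.00260; adjusted p = 0.708 with an estimated correlation), neocortex markers a median of 0.12 with 10 of 15 higher (adjusted p = 0.0122; adjusted p = 0.612 with an estimated correlation), and adult neurogenesis genes a median of 0.08 with 10 of 14 higher (adjusted p = 0.0409; adjusted p = 0.536 with an estimated correlation). No member of the last 3 lists passed over all genes or adjusted over the list alone. These calls were not stable to single animals: the immediate early call ended without KO1 (adjusted p = 0.0528), the microglia call without WT2 (adjusted p = 0.101) and without KO1, where its direction turned (adjusted p = 0.993), and the neocortex call without WT1 (adjusted p = 0.101), without KO1 (adjusted p = 0.384) and after quantile normalization (adjusted p = 0.0883). The neurogenesis call ended without WT1 (adjusted p = 0.101), without KO2 (adjusted p = 0.127), after median-of-ratios scaling (adjusted p = 0.0630) and with a minimum of 1 FPKM (adjusted p = 0.0571). With 1 animal left out, the medians were 0.06 to 0.25 for immediate early genes and 0.02 to 0.25 for neocortex markers. Choroid plexus and blood markers (medians -2.17 and -0.95) were lower in the same animals.

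In total, camera called 17 of the 38 lists, 12 higher and 5 lower in the animals labelled KO. With an estimated correlation 0 lists were called. The rotation test fry, which asks whether a set moves on balance one way, also called 0 (smallest adjusted p = 0.190). The estimated correlation was 0.864 for choroid plexus and 0.942 for blood markers, far above the preset 0.01. It was below 0 for some called lists, such as calcium channels (-0.048) and glutamate receptors (-0.031), which also lost their call. The loss of calls therefore does not rest on a high correlation alone. With an estimated correlation, camera has only the degrees of freedom that 4 animals leave, and fry rests on the same 4 animals. Both have little power here: choroid plexus markers, with all 22 members lower, reached an adjusted p of 0.587 in camera with an estimated correlation. The 0 calls therefore do not show that the lists are unchanged.

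**Figure D4:**
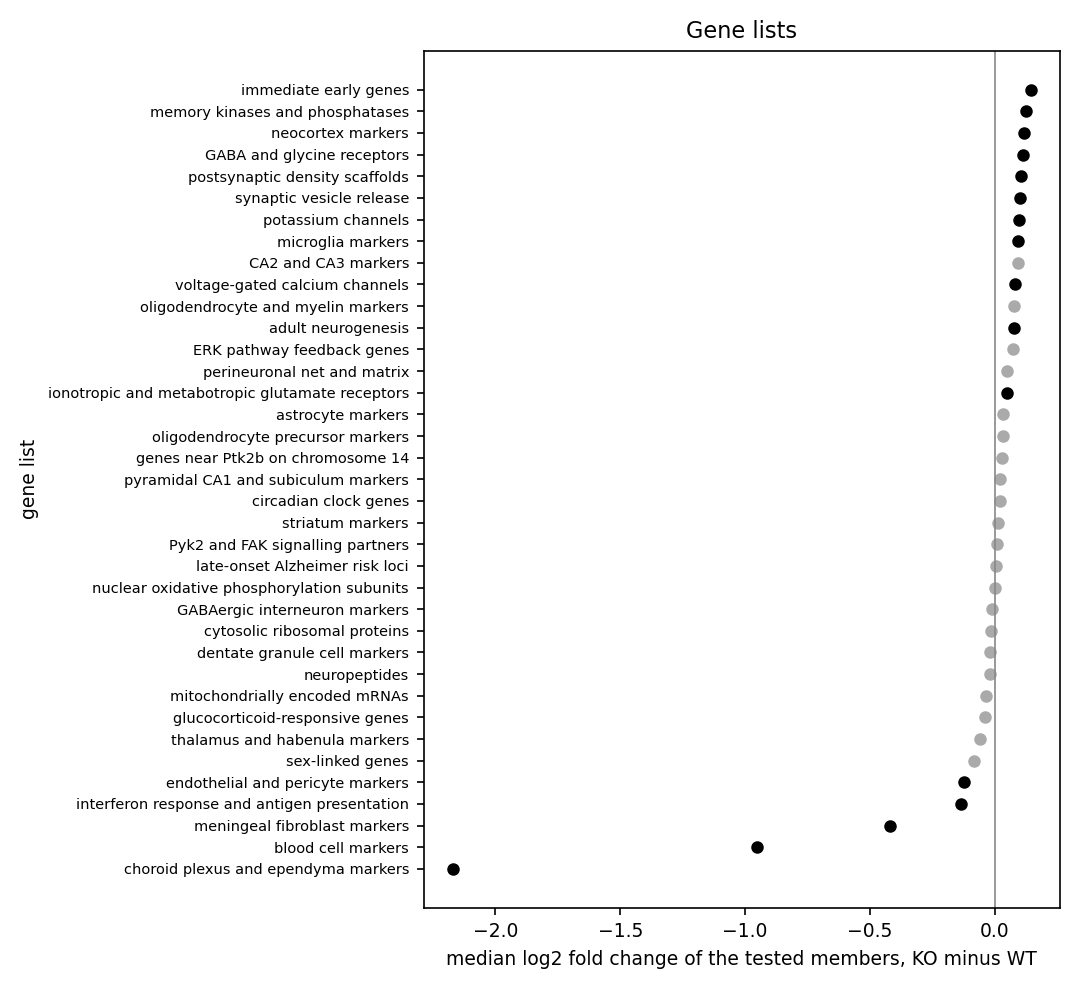
Median log2 fold change of the measured members, animals labelled KO minus WT (horizontal), for the gene lists reported here (vertical); black marks lists with a camera adjusted p under 0.05 at the preset correlation and grey the others. The medians reach from -2.17 for choroid plexus and ependyma markers to 0.14 for immediate early genes.

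The other 21 lists did not pass as sets, but some of their members did when adjusted over the list alone. Glucocorticoid-responsive genes (camera adjusted p = 0.331) held 4 that fell, Sgk1, Pdk4, Nfkbia and Arrdc2, with Sgk1, a stress-induced kinase, at 57.9 ± 5.16 FPKM in WT and 42.6 ± 2.08 FPKM in the animals labelled KO. Striatum markers (0.315) held 3 that fell, Ppp1r1b, the opioid peptide precursor Penk and the transcription factor Six3, of which Ppp1r1b also passed over all genes. Among CA2 and CA3 markers (0.131) Coch and Map3k15 fell and Cpne4 rose. Among late-onset Alzheimer risk loci (0.815) Ace fell from 28.7 ± 4.35 to 5.37 ± 2.90 FPKM and Clu from 591 ± 3.42 to 512 ± 10.7 FPKM. Ace, at 25.6 and 31.8 FPKM in WT1 and WT2 and 3.31 and 7.42 FPKM in KO1 and KO2, follows the animal order of the choroid plexus marker Folr1, at 43.6, 55.9, 2.38 and 11.7 FPKM. Of all genes, 50.9% were higher in WT2 than in WT1 and 58.0% higher in KO2 than in KO1. The shared order alone therefore does not show a choroid plexus source. Spry2, a brake on growth factor signalling, rose among ERK feedback genes (0.0789), and Trf, the transferrin gene, fell among oligodendrocyte and myelin markers (0.110). Apart from Ppp1r1b, none of these members passed over all genes.

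No member passed, adjusted over the list alone, in the lists of Pyk2 and FAK signalling partners (camera adjusted p = 0.098), perineuronal net and matrix (0.137), astrocytes (0.156), CA1 and subiculum (0.156), dentate granule cells (0.298), GABAergic interneurons (0.310), oligodendrocyte precursors (0.418), circadian clock genes (0.575), neuropeptides (0.596), nuclear oxidative phosphorylation (0.815), thalamus and habenula (0.886), mitochondrially encoded mRNAs (0.886) and cytosolic ribosomal proteins (0.921). After quantile normalization the ribosomal and oxidative phosphorylation lists passed as lower sets at the preset correlation (camera adjusted p = 0.000446 and 0.00507). Without that normalization their estimated correlations were 0.719 and 0.263 (camera adjusted p = 0.985 and 0.958 with these). The sex-linked list (0.575) held 1 measured gene, Xist, at 71.2 ± 0.418 FPKM in WT and 67.3 ± 4.99 FPKM in the animals labelled KO. Median, mean and test differed in sign for 13 of the 21 lists, namely Pyk2 and FAK partners, neuropeptides, circadian clock, mitochondrially encoded, oxidative phosphorylation, ribosomal, Alzheimer, perineuronal net, oligodendrocyte precursor, dentate, interneuron, striatum and the genes near Ptk2b. Changes in either direction, tested by the mixed form of fry, passed for 4 lists at an adjusted p of 0.0491, namely oxidative phosphorylation, Alzheimer, striatum and the genes near Ptk2b.

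With all animals kept, 0 lists were called with an estimated correlation, which was 0.863 for oligodendrocyte and 0.520 for dentate markers. At the preset correlation of 0.01, the direction of the test turned without KO1 for oligodendrocyte and CA1 markers and without WT2 for dentate markers. For ribosomal proteins it turned without WT2 and without KO1. Under other choices of the animal left out, these and some other uncalled lists passed as higher sets. Oligodendrocyte and myelin markers did so without WT1 (adjusted p = 0.0135) and without KO2 (0.000356), and dentate granule cell markers without WT1 (0.00319) and without KO1 (0.0347). CA1 and subiculum markers passed without WT2 (0.0239) and without KO2 (0.00364), ERK feedback genes without WT2 (0.0224) and without KO2 (0.0105), and CA2 and CA3 markers without WT1 (0.00395). Astrocyte markers (0.0128) and ribosomal proteins (0.0355) passed without KO2. Glucocorticoid-responsive genes passed as a lower set without KO1 (0.0288).

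Genes beside Ptk2b on chromosome 14 were examined because a targeted allele can carry flanking DNA of another strain. Of the 82 tested genes that start within 5 Mb of Ptk2b, 0 were called by limma, which with 9 calls among all genes says little about flanking DNA. At an unadjusted p under 0.05 there were 11, 3 higher and 8 lower, or 13.4% against 15.6% elsewhere (two-sided Fisher's exact p = 0.759). By the same Fisher's exact test the share was 25% against 15.5% within 2 Mb (7 of 28 genes, p = 0.187), 14.6% against 15.5% within 10 Mb (p = 0.822) and 17.6% against 15.5% within 20 Mb (p = 0.301). The fixed list of neighbours (camera adjusted p = 0.310) held 36 measured genes, of which 2 rose and 4 fell when adjusted over the list alone and 0 passed over all genes. Sorbs3, an adaptor of focal adhesions (ENSMUSG00000022091, chromosome 14, 70180468 to 70211989), fell from 10.9 ± 0.0473 FPKM in WT to 6.82 ± 0.247 FPKM in the animals labelled KO, a log2 fold change of -0.60 (SE 0.06, adjusted p = 0.0798 over all genes). Clu, Gnrh1 and Scara5 fell too, while the neurofilament genes Nefl and Nefm rose by 0.19 and 0.15 on the log2 scale (SE 0.03 each). Gnrh1 (1.20 ± 0.0615 to 0.309 ± 0.264 FPKM) and Scara5 (0.937 ± 0.318 to 0.194 ± 0.158 FPKM) were near the floor. Both animals labelled KO lay below the minimum of 0.5 FPKM for these genes, which passed the filter through WT alone. The annotated spans of Nefl and Nefm overlap, so their reads cannot be fully separated.

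Technical replicates of 1 animal differed less than animals did. Judged by the deposited confidence intervals, a median of 7.72% of genes lay outside the 95% range of their difference between technical replicates (7.54% to 8.06% over the 4 pairs), against 19.1% between animals of 1 group and 26.1% between animals of different groups. The median SD of the log2 difference was 0.13, 0.17 and 0.24 for these kinds of pair. The technical replicates were averaged and counted as 1 animal.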

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

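Count-based tests planned as alternatives were not run, because no counts were used. Alternatives chosen after seeing the data were quantile normalization, at least 5 FPKM, genes of at least 200 bp, protein-coding genes, marker lists left out, mean of log2 values, no variance trend and KO1 without its first library. The 9 calls lay lower in the animals labelled KO under every alternative in which they were tested. Each already had both animals labelled KO below both WT animals, so leaving out an animal or changing the filter could not turn it. The number of calls depended on the setting, and except for fewer animals or other genes tested the cause was not tested. It was 13 after median-of-ratios scaling, 10 after quantile normalization, 8 at 1 FPKM and 7 without the marker lists. With no filter it was 0, all lower calls lost, and at an adjusted p under 0.01 also 0; without a variance trend it was 1. It was 14 with a pseudocount of 0.1 (1 higher, 13 lower), 19 with first technical replicates (2 higher, 17 lower), 35 with second ones (6 higher, 29 lower), and 2053 with all 8 libraries as if independent (628 higher, 1425 lower), where technical replicates count as animals. With all 8 libraries with animal as a random effect it was 1088 (276 higher, 812 lower). That fit uses 1 correlation within animals for all genes, so technical replicates still count in part as animals for genes that vary more between animals. At an adjusted p under 0.1 the number of calls was 175 (10 higher, 165 lower), with mean log2 values 16 (1 higher, 15 lower) and without the first library of KO1 20 (4 higher, 16 lower). Restricting genes gave 20 (at least 200 bp), 37 (protein-coding) and 17 (at least 5 FPKM), all lower. Leaving out 1 animal gave 0 to 128 calls, 0 to 14 higher and 0 to 114 lower, and a Ptk2b log2 difference of 0.24 to 0.43. Ptk2b passed the threshold only with all 8 libraries as units, at 0.33 both as if independent and with animal as a random effect (adjusted p = 0.00398 and 0.00634; 0.0842 to 0.485 elsewhere).

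With the animal number as a block 184 genes were called (8 higher, 176 lower) and 1 near Ptk2b. The labels give no shared litter, batch or day, so the animals were taken to share only a number. WT2 minus WT1 and KO2 minus KO1 correlate at 0.107 across genes, which are not independent, and 2 pairs cannot show or exclude pairing. Under the block the tests of mitochondrially encoded mRNAs (median -0.036) and ribosomal proteins (-0.016) turned direction. The set of neurogenesis genes was no longer called under the block (adjusted p = 0.0584), and oligodendrocyte and myelin markers were called as higher (adjusted p = 0.0465). Both values are from camera at the preset correlation. With an estimated correlation and no block they were 0.536 and 0.820. Near Ptk2b, 10 genes were called with libraries as if independent, 7 with animal as a random effect, 1 at an adjusted p under 0.1, 1 among protein-coding genes and 0 at 2, 10 and 20 Mb. The share of genes beyond the intervals of technical replicates moved from 7.72% to 8.42% at 50 implied fragments.

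List calls fell from 17 (12 higher, 5 lower) to 0 in both directions with an estimated correlation and with fry. They were 14 to 17 under the other alternatives that keep all animals, and 15 to 19 (10 to 15 higher, 4 to 6 lower) with 1 animal left out. Uncalled lists turned direction in some tests. With fry these were neuropeptides (median -0.020), clock (0.020), mitochondrially encoded (-0.036), oxidative phosphorylation (0.00086), ribosomal (-0.016) and neighbours of Ptk2b (0.028); at 1 FPKM ribosomal (-0.016). Quantile normalization turned oxidative phosphorylation (-0.021), ribosomal (-0.034), astrocyte (0.026) and thalamus (0.039) lists, and mt-Nd6 (0.044). Without the first library of KO1, mitochondrially encoded (-0.040) and thalamus (-0.035) lists turned, and with first technical replicates Bmp4 (0.15). With 1 animal left out, tests turned for these ranges: Bmp4 -0.55 to 0.0024, Man1a -0.32 to 0.0097, glucocorticoid -0.10 to 0.010, clock -0.059 to 0.054, interferon -0.29 to -0.032, mitochondrially encoded -0.057 to -0.012, oxidative phosphorylation -0.019 to 0.013, ribosomal -0.047 to 0.015, Alzheimer -0.021 to 0.0069, microglia -0.0077 to 0.19, oligodendrocyte -0.027 to 0.13, CA1 -0.044 to 0.093, dentate -0.089 to 0.087, thalamus -0.13 to -0.061 and sex-linked -0.16 to -0.0082. The cause was not tested.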

Other observations

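All tests in this part were chosen after the results were seen, although median-of-ratios scaling, which 1 of them uses, was an alternative set before for counts and applied here to FPKM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty reached at most 0.0621 FPKM in any library, while Xist lay between 63.7 and 71.5 FPKM in all 4 animals.

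Ptk2b was 26.0% higher in the animals labelled KO. An exchange of labels with an allele that removes the transcript is argued against by the lowest library holding 0.722 of the highest. Reads of the related gene Ptk2 counted for Ptk2b could not be tested with these values. Ptk2 reached at most 0.117 of the Ptk2b FPKM in a library, but reads moved to Ptk2b would themselves lower the Ptk2 value. An allele that stops the protein and leaves the transcript level as it is stays open, with a KO over WT ratio of 1.26 and no overlap between the groups, and animals labelled KO that carry an intact gene would give the same kind of value. Gene-level values cannot decide between these.

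Choroid plexus and ependyma genes were lower in the animals labelled KO. Scaling of the libraries is argued against, since the list median stayed at -2.16 on the log2 scale after median-of-ratios scaling, whose factors were 0.984 to 1.01. Different amounts of choroid plexus in the dissected pieces may account for the pattern: between the 2 animals of a group, 90.5% of comparisons of the 21 other members moved with Ttr (17 of 21 in WT, 21 of 21 among those labelled KO, against 50.9% and 58.0% of all genes), and Ttr itself differed 5.19-fold between the animals labelled KO. In WT, Rarres2, Foxj1, Tmem212 and Ccdc153 did not move with Ttr (WT2 over WT1 of 0.774, 0.961, 0.730 and 0.748). The comparisons rest on 2 pairs of animals and on genes that vary together. Markers of 1 tissue would also move together if something else changed that tissue, so the share cannot name the cause. Of the 22 members, 16 were at 1 FPKM or more in every animal and 1 is on another list. An effect of genotype on the choroid plexus was not tested and stays open, as the dissection and the genotype cannot be separated with 2 animals per group.

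Haemoglobin genes were lower in the animals labelled KO, with similar levels in both of them. The same choroid plexus tissue as their source could not be settled: the change of the 4 globins with Ttr within a group predicted a median of 29.5% of the gap between groups, with a range of 15.9% to 61.2% over 8 predictions. Less blood left in the tissue also stays open, since Alas2, a red cell gene outside the globins, was 1.84 times higher in WT but lay near 1 FPKM or below. A difference of genotype was not tested.

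The 4 animals can be split 2 against 2 in 3 ways, too few for a share under 0.05. The real split called 9 genes and 1 split in all reached that number, and the others called 6 and 1. At an unadjusted p under 0.05 the real split had 2591 genes and the others 232 and 477. The other splits put WT and KO animals in the same group, so any difference between WT and KO widens their spread and lowers their counts. Both unadjusted counts lay below the 833 expected if no gene differed. The other splits are therefore no reference for what chance gives.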
